A study of Mus musculus with 30 samples.

How the data were processed

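The 30 samples were grouped by their labels into 10 groups of 3. The time course held CALM/AF10 leukemia cells and GMP at 0, 6 and 10 h of RG3039, and the second part held the 4 AML lines. STAR and the mm10 genome build are named in the submitters' processing notes, with no version and no role. Libraries were made from total RNA with the Ovation Mouse RNA-Seq System, per the labels' protocols. For the time course the authors deposited TPM values per gene, in 1 table of 31854 genes for CALM/AF10 cells and another of 34406 genes for GMP, without naming the quantifier or the annotation. Their columns carry the group but no replicate number, so their samples are called a, b and c here in column order. For each line sample the authors deposited TPM and estimated counts of reads per transcript, per the file headers, for 99567 transcripts with versioned Ensembl identifiers. For the junctions the authors deposited 4 tables, each comparing 6 h or 10 h with 0 h in 1 cell type. Per the file headers these give the percent spliced in (PSI) of each junction as a group mean rounded to whole percent, a log2 ratio, a q-value and the mean raw count. The mean raw count is used here as a score of how much evidence a junction has, since the deposited value is an average over a group and not the count of 1 library. The values show that the log2 ratio is the ratio of the PSI odds after against before treatment. Each table lists only junctions with q under 0.05 and a positive ratio, per the deposited values.

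Depth is unknown for the time course, because each TPM column adds up to 1000000. The lines had 8739673 to 25194822 estimated reads. Their transcripts were assigned to genes with the GENCODE M21 annotation, which held 98206 of the 99567, and 0.749 to 1.19 percent of the estimated reads fell on the others and were left out. Estimated counts were summed per gene (32485 genes) and rounded.

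The design, the 35 gene lists, the alternatives and the rule for naming genes were written before the data were examined. Genes were kept where at least 3 of the fitted samples had a TPM of 1 or more. Time-course values were taken as log2(TPM + 1) and fitted with limma 3.58.1 (moderated test with a mean-variance trend) in R 4.3.3, with all groups of a cell type in a single fit. The difference between cell types was tested in a fit of both tables on the symbols they share, as the change in CALM/AF10 cells minus the change in GMP. Lines of the same fusion were compared with the edgeR 4.0.16 quasi-likelihood test after TMM scaling. For MLL/AF9 against CALM/AF10 the counts were summed per line, so that 2 lines per fusion were the replicates. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. No edgeR or DESeq2 test was run on the TPM tables.

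A test of untreated CALM/AF10 cells against GMP had also been planned, on condition that both tables listed the same genes. It was run, and it was set aside after its values had been seen, because the tables list different genes and some abundant genes, such as Rps12, differ between them by amounts that the counting could make. Untreated levels are therefore given side by side without a test, and its calls enter no count here. The test of the difference of changes compares each table only with itself, but the pseudocount still acts differently on genes whose level differs between the tables.

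Gene lists were tested with camera in limma, with the preset inter-gene correlation of 0.01 and again with the correlation estimated from the data. Symbols of the lists were looked up in the whole table, with older names as a fallback, before the filter was applied, and a list was tested where 5 or more of its genes were kept. Its p-values were adjusted over the lists of a comparison. The lists covered the cap and mRNA turnover (cap binding, mRNA decapping and 5-prime decay, exosome, nonsense-mediated decay), splicing (spliceosome core, SR and hnRNP splicing regulators), the leukemia program (HOXA and MEIS, HOXB, stem and progenitor genes), growth, cell cycle and stress programs, and markers of other blood, stromal and endothelial cells.

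In each comparison Dcps, Hoxa9, Meis1 and Myc were named whatever their values. Besides them the rule took the 6 largest rises and the 6 largest falls among called genes with a mean TPM of at least 5 in the higher group and no overlap between the groups. It also took up to 4 called members of each list with at least 3 called members or a camera adjusted p under 0.05. Of the junction tables it took the 8 smallest q-values and the list members shared by both tables of a cell type. Predicted genes, clone names and pseudogenes were counted but not named. The text leaves out some genes the rule takes, mainly immunoglobulin and T cell receptor segments, antisense genes and close paralogs, whose reads the counting could have split. A few single-gene results are not reported here.

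The expression of genes with a listed junction was compared with camera and with 10000 random lists matched on mean expression. The share of each list with a junction was set against the same kind of random lists. Genes with a junction predicted to lead to decay were set against the other genes with a junction by a permutation test with 100000 resamples. Junction positions are in mm10 as the tables give them, and their place was read from GENCODE M21. To see what shared 0 h samples alone would give, 100 sets of unchanged groups were simulated against them. A test of scaling on immediate early, NF-kB and heat shock genes together was run in 2 forms after their values were seen, and it was set aside because neither form could decide.

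The tests were checked on simulated data with 100 genes changed by each of 2 known folds. These genes were drawn from the better expressed ones, so the shares below do not hold for genes near the filter. In the simulation of CALM/AF10 cells at 6 h, limma recovered 74 percent of genes changed 1.5-fold and 98 percent of those changed 2-fold, and in GMP at 10 h 56 and 92 percent. For the difference of the 6 h changes these shares were 44 and 86 percent. For CALM/AF10 lines edgeR recovered 62 and 76 percent and for MLL/AF9 lines 56 and 82 percent. In the comparison of the fusions it recovered 47 percent of genes changed 4-fold and 92 percent of those changed 16-fold.

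The alternatives were a pseudocount of 0.1, no filter on low values, a minimum of 5 TPM, median centring, quantile normalization, a fit of only the 2 groups compared, leaving out each replicate, DESeq2 size factors, a replicate block and line as a random effect. Added after the data were seen were scaling by library size without TMM, limma on log2(TPM + 1) of the lines, DESeq2 1.42.0, leaving out each line, and the overlaps of calls under each setting. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.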

Results

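RNA sequencing measured mRNA in 30 mouse samples, in 10 groups of 3. A time course followed the response to RG3039, a small molecule inhibitor of Dcps, the scavenger enzyme that hydrolyses the cap left over from mRNA decay. It held leukemia cells that carry the CALM/AF10 fusion and normal granulocyte-macrophage progenitors (GMP), each before treatment (0 h) and 6 h and 10 h after it, at 1 µM per the file headers. The second part held 4 mouse acute myeloid leukemia lines with 3 samples each, CALM/AF10 lines 1 and 2 and MLL/AF9 lines 1 and 2. The labels do not say whether the 3 samples of a group came from separate cultures, so they may be technical replicates. The time course came as TPM, a length-scaled measure of transcript abundance that adds up to 1000000 per sample, which leaves its depth unknown. The lines had 8739673 to 25194822 estimated reads per sample. Changes below are log2 differences with their standard error, and levels are mean TPM ± SD of 3 samples per group unless stated. In the time course the change was taken on log2(TPM + 1), which understates the fold of genes with low TPM. There were no untreated time-matched samples at 6 h or 10 h, so a change over time holds the effect of the drug and of time in culture together.

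The first comparison asked how CALM/AF10 leukemia cells responded within 6 h of Dcps inhibition. Among the steepest falls were those of Fam117a (from 19.0 ± 1.33 to 1.88 ± 0.326 TPM), Apba1, an adaptor of vesicle traffic (from 6.08 to 0.0927 TPM), and Pde6d, a carrier of prenylated proteins (from 15.4 to 2.06 TPM). Mcu, the pore of the mitochondrial calcium uniporter, fell from 12.5 ± 0.733 to 1.95 ± 0.219 TPM, and the kinase gene Aatk fell from 14.7 to 1.97 TPM. Rhbdd3, a rhomboid family protein, rose from 10.9 to 35.8 TPM, and the tRNA methyltransferase gene Trmt10a rose from 3.23 ± 0.287 to 12.1 ± 0.129 TPM. The target gene itself did not pass, as Dcps stood at 15.4 ± 1.13 TPM before treatment and 17.7 ± 1.15 TPM at 6 h (limma, log2 change 0.18 ± 0.07, adjusted p = 0.132), though it did after median centring (adjusted p = 0.0490). Srrt, which links the nuclear cap-binding complex to RNA processing and decay, fell from 77.7 ± 3.77 to 41.5 ± 3.04 TPM (log2 change -0.89 ± 0.06, adjusted p = 3.48e-05 in limma). In limma the log2 changes of Fam117a, Apba1, Pde6d, Mcu and Aatk were -2.80, -2.70, -2.42, -2.20 and -2.40, and those of Rhbdd3 and Trmt10a were 1.65 and 1.63, with adjusted p = 1.18e-06 to 0.000135. The leukemia transcription factor genes moved less. Myc fell from 504 ± 5.18 to 439 ± 8.60 TPM (log2 change -0.20 ± 0.04, adjusted p = 0.0140 in limma). Hoxa9 fell from 186.9 to 165 TPM (log2 change -0.18 ± 0.05, adjusted p = 0.0394 in limma), and Meis1 did not pass the threshold (log2 change -0.11 ± 0.05, adjusted p = 0.176 in limma). The calls of Myc and Hoxa9 were lost when some single samples were left out. That of Myc was also lost after quantile normalization, and that of Hoxa9 after median centring and without the filter on low values. Erg, a transcription factor of stem and progenitor cells, fell from 16.8 ± 0.878 to 9.32 ± 0.343 TPM (log2 change -0.79 ± 0.07). Of 12815 genes tested by limma at an adjusted p under 0.05, 697 rose and 915 fell, and centring on the median gene turned this split to 1031 and 731.

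Growth and biosynthesis genes led the falling lists in CALM/AF10 cells at 6 h. Of 34 MYC and ribosome biogenesis genes, 8 fell, Nop2 and Srm among them, and none rose (17 lower adjusted over the list alone). The list as a whole was lower (mean log2 change -0.16, camera adjusted p = 4.20e-06, adjusted p = 0.720 with an estimated correlation). Of 35 DNA replication and G1/S genes, 5 fell, among them Uhrf1 and Chaf1a, and E2f2 rose (1 higher and 7 lower adjusted over the list alone; mean log2 change -0.16, camera adjusted p = 0.000281, adjusted p = 0.720 with an estimated correlation). The ATF4 list, which serves amino acid supply under stress, had 9 of 37 genes lower, including Atf4 itself (from 207 ± 3.43 to 164 ± 7.95 TPM) and Pck2, and 1 higher, the cystine transporter gene Slc7a11 (2 higher and 14 lower adjusted over the list alone; mean log2 change -0.13, camera adjusted p = 0.00392, adjusted p = 0.720 with an estimated correlation). Unfolded protein genes of the endoplasmic reticulum had 4 of 23 members lower, such as Herpud1 and Canx (5 lower adjusted over the list alone; mean log2 change -0.09, camera adjusted p = 0.0397, adjusted p = 0.720 with an estimated correlation). The cytosolic heat shock list had 3 of 15 lower, including Hsp90aa1 (5 lower adjusted over the list alone; mean log2 change -0.12, camera adjusted p = 0.0401, adjusted p = 0.720 with an estimated correlation). Of 28 replication-dependent histones, near-identical copies whose single members are uncertain, 4 fell (4 lower adjusted over the list alone; mean log2 change -0.09, camera adjusted p = 0.0397, adjusted p = 0.785 with an estimated correlation). These last 3 lists lost their call when changes were centred on the median gene. Among cell death genes of the BCL2 family, 3 of 15 rose, namely Bcl2l11, Bcl2l1 and Bbc3, the last of which lost its call without some single samples or without the filter, and the list did not pass (3 higher and 1 lower adjusted over the list alone; mean log2 change 0.10, camera adjusted p = 0.0839). Bcl2l11, which encodes BIM, rose from 23.4 ± 1.40 to 32.5 ± 1.53 TPM (log2 change 0.46 ± 0.06, adjusted p = 0.00128 in limma). Nqo1, an NRF2 target, fell from 12.7 ± 0.171 to 6.69 ± 0.392 TPM, yet the NRF2 list of 18 genes did not pass (mean log2 change -0.04, camera adjusted p = 0.885). In the splicing lists 8 of 38 SR and hnRNP regulators fell, such as Srsf4, without a call for the list (12 lower adjusted over the list alone; mean log2 change -0.09, camera adjusted p = 0.0554). The limma log2 changes were -0.28 for Nop2, -0.23 for Srm, -0.30 for Uhrf1, -0.27 for Chaf1a, 0.42 for E2f2, -0.48 for Pck2, 0.48 for Slc7a11 and -0.36 for Hsp90aa1.

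At 10 h some of the steepest falls in CALM/AF10 cells remained, and interferon genes had risen. Fam117a stood at 1.69 ± 0.278 TPM and Mcu at 1.71 ± 0.0515 TPM, against 19.0 ± 1.33 and 12.5 ± 0.733 before treatment (log2 change -2.90 ± 0.11, adjusted p = 6.63e-07 and log2 change -2.31 ± 0.09, adjusted p = 6.25e-07 in limma). Dcp2, the enzyme that removes the cap from intact mRNA, rose from 47.3 ± 5.12 to 99.9 ± 7.86 TPM (log2 change 1.06 ± 0.08, adjusted p = 3.44e-05 in limma). Its cofactor gene Dcp1b fell from 6.34 ± 0.759 to 1.86 ± 0.376 TPM (log2 change -1.36 ± 0.13, adjusted p = 0.000106 in limma). Dcps rose slightly, from 15.4 ± 1.13 to 18.8 ± 0.951 TPM (log2 change 0.27 ± 0.07, adjusted p = 0.0255 in limma), and Srrt stayed low (log2 change -0.70 ± 0.06, adjusted p = 9.80e-05 in limma). Tkfc, which phosphorylates dihydroxyacetone, rose from 8.19 ± 0.482 to 31.1 ± 1.18 TPM (log2 change 1.81 ± 0.06, adjusted p = 4.73e-07 in limma). Myc did not pass against its start (log2 change -0.06 ± 0.04, adjusted p = 0.389 in limma), and Hoxa9 and Meis1 were each lower by 0.18 on the log2 scale (adjusted p = 0.0276 and 0.0234 in limma). The calls of Dcps, Hoxa9 and Meis1 at 10 h were lost without some single samples. Those of Hoxa9 and Meis1 were also lost in a fit of the 0 h and 10 h samples alone, and that of Hoxa9 after median centring and without the filter. Of 12815 genes, limma called 1349 higher and 1107 lower at 10 h, and 1203 and 1235 after quantile normalization.

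The ATF4 list was lower at 10 h, with 20 of 37 genes lower and 1 higher (2 higher and 27 lower adjusted over the list alone; mean log2 change -0.33, camera adjusted p = 1.27e-11, adjusted p = 0.157 with an estimated correlation). Cth, which makes cysteine, fell from 6.95 ± 0.0587 to 1.37 ± 0.193 TPM and Atf5 fell from 62.6 ± 1.74 to 33.0 ± 1.04 TPM (log2 change -1.75 ± 0.10 and -0.90 ± 0.05). Type I interferon genes turned up, 24 of 37 higher and none lower (30 higher adjusted over the list alone; mean log2 change 0.59, camera adjusted p = 1.50e-11, adjusted p = 0.575 with an estimated correlation). Among them the RNA sensor gene Dhx58 rose from 7.14 ± 0.222 to 15.6 ± 2.30 TPM. Oas3, which makes an activator of RNase L, rose from 7.08 ± 0.595 to 17.1 ± 3.95 TPM, and Rtp4 rose from 6.77 to 13.1 TPM (log2 change 1.01 ± 0.10, 1.14 ± 0.14 and 0.84 ± 0.13). Cholesterol biosynthesis genes were higher in 9 of 23 cases and lower in none (9 higher adjusted over the list alone; mean log2 change 0.21, camera adjusted p = 1.53e-05, adjusted p = 0.157 with an estimated correlation). The regulator gene Srebf2 rose by 0.31 on the log2 scale. In the spliceosome core 10 of 39 genes rose and none fell (12 higher adjusted over the list alone; mean log2 change 0.12, camera adjusted p = 0.00262, adjusted p = 0.387 with an estimated correlation). Sf3b5 rose by 0.43 and Zrsr2 by 0.55 on the log2 scale. Histones had 12 of 28 genes lower (18 lower adjusted over the list alone; mean log2 change -0.21, camera adjusted p = 5.83e-08, adjusted p = 0.563 with an estimated correlation). Lists without a call still held single changes. In the NRF2 list 5 of 18 genes fell, Nqo1 from 12.7 ± 0.171 to 5.46 ± 0.366 TPM and Hmox1 from 99.4 to 62.7 TPM, and 2 rose (4 higher and 7 lower adjusted over the list alone; mean log2 change -0.19, camera adjusted p = 0.113). In the list of mRNA decapping and 5-prime decay, 4 of 22 genes rose and 1 fell (4 higher and 1 lower adjusted over the list alone; mean log2 change 0.09, camera adjusted p = 0.143). Among 18 cap binding genes 2 rose and 4 fell (2 higher and 4 lower adjusted over the list alone; mean log2 change -0.04, camera adjusted p = 0.588). The HOXA and MEIS program had 5 of 25 members higher and 5 lower (mean log2 change -5.18e-05, camera adjusted p = 0.438). Ribosomal protein genes had a mean change of 0.12 while their test pointed down (camera adjusted p = 0.438), with 3 of 43 higher and 4 lower.

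Between 6 h and 10 h antiviral and sterol genes rose and amino acid supply genes fell in CALM/AF10 cells. Oasl2 rose from 14.4 ± 3.06 to 32.7 ± 7.97 TPM, Oas3 rose from 7.36 ± 0.840 to 17.1 ± 3.95 TPM and Slfn5 rose from 13.2 to 26.6 TPM, with log2 changes of 1.12 ± 0.18, 1.10 ± 0.14 and 0.95 ± 0.13 and adjusted p = 0.00795 to 0.0156 in limma. Slc7a11, higher at 6 h, then fell from 7.38 ± 0.729 to 2.79 ± 0.292 TPM (log2 change -1.14 ± 0.10, adjusted p = 0.00120 in limma). Only 9 of 37 interferon genes passed over all genes, against 31 higher and 1 lower adjusted over the list alone (mean log2 change 0.57, camera adjusted p = 9.54e-17, adjusted p = 0.210 with an estimated correlation). Of 23 cholesterol biosynthesis genes 10 rose and none fell (18 higher adjusted over the list alone; mean log2 change 0.30, camera adjusted p = 1.38e-13), and this was the 1 list of 30 that kept its call with the estimated correlation (adjusted p = 0.0275). The ATF4 list fell further, 12 of 37 genes lower (1 higher and 16 lower adjusted over the list alone; mean log2 change -0.20, camera adjusted p = 1.17e-10, adjusted p = 0.105 with an estimated correlation). DNA replication genes rose in 7 of 35 cases (17 adjusted over the list alone). Their mean log2 change was 0.17 (camera adjusted p = 1.03e-07, adjusted p = 0.147 with an estimated correlation). Of 34 MYC and ribosome biogenesis genes 3 rose (12 higher adjusted over the list alone; mean log2 change 0.15, camera adjusted p = 4.04e-07, adjusted p = 0.168 with an estimated correlation). Of 12815 genes, limma called 280 higher and 96 lower. That count rested on single samples. It was 64 to 263 when 1 sample was left out (with Oasl2 no longer called without either of 2 samples at 6 h, nor without the filter), 188 without the filter on low values and 140 when only the 6 h and 10 h samples entered the fit. The split turned with the scaling, to 194 higher and 153 lower after median centring and 119 and 154 after quantile normalization.

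Normal GMP changed far more genes after RG3039 than the leukemia cells did. At 6 h the steepest rises included Tarm1, a receptor of myeloid cells (from 2.60 ± 0.465 to 136 ± 2.11 TPM), Lpl, which encodes lipoprotein lipase (from 0.976 ± 0.350 to 70.8 ± 2.31 TPM), and the chemokine gene Ccl5 (from 26.9 ± 10.6 to 487 ± 22.0 TPM). Steep falls came in genes of acute stimulation, such as Fosb (from 63.5 ± 4.67 to 0.720 ± 0.191 TPM), the neutrophil chemokine gene Cxcl2 (from 47.5 to 0.457 TPM), the phosphatase gene Dusp1 (from 126 to 4.10 TPM) and Tnfaip3, a brake on NF-kB (from 53.2 to 5.14 TPM). In limma these 7 genes had log2 changes of 5.25, 5.20, 4.19, -5.23, -5.07, -4.65 and -3.16, with adjusted p = 5.30e-09 to 7.35e-06. Myc rose from 339 ± 12.2 to 1021 ± 21.8 TPM (log2 change 1.59 ± 0.05, adjusted p = 3.59e-08 in limma). Dcps, Hoxa9 and Meis1 did not pass the threshold, at 45.0 ± 2.73 TPM before and 44.0 ± 10.6 TPM at 6 h for Dcps (adjusted p = 0.767, 0.566 and 0.854 in limma). Without 1 of the 6 h samples Dcps was called lower (log2 change -0.24, adjusted p = 0.0332 in limma). The cell cycle inhibitor gene Cdkn1a rose from 15.6 ± 0.232 to 57.7 ± 1.05 TPM (log2 change 1.83 ± 0.05, adjusted p = 2.78e-08 in limma). The splicing kinase gene Clk1 fell from 56.7 ± 6.03 to 15.4 ± 2.44 TPM (log2 change -1.82 ± 0.12, adjusted p = 3.81e-06 in limma). Dcp1b fell as in the leukemia cells, from 9.53 ± 1.18 to 5.01 ± 0.324 TPM (log2 change -0.80 ± 0.11, adjusted p = 0.000402 in limma). Of 14246 genes, limma called 3429 higher and 2839 lower.

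All 24 cholesterol biosynthesis genes tested in GMP rose at 6 h (24 higher adjusted over the list alone; mean log2 change 1.96, camera adjusted p = 6.83e-19). Idi1 rose from 7.68 ± 1.05 to 63.5 ± 1.26 TPM and Mvd from 5.01 to 35.7 TPM (log2 change 2.90 ± 0.09 and 2.61 ± 0.07). Of 34 MYC and ribosome biogenesis genes, 33 rose and none fell (33 higher adjusted over the list alone; mean log2 change 0.85, camera adjusted p = 3.95e-17). The spermidine synthase gene Srm rose from 190.0 to 505 TPM and Nop2 from 26.2 to 70.0 TPM. In the ATF4 list 27 of 36 genes rose and 5 fell (27 higher and 5 lower adjusted over the list alone; mean log2 change 0.58, camera adjusted p = 7.51e-07). The asparagine synthetase gene Asns rose from 7.54 to 34.4 TPM. Immediate early genes went the other way, 19 of 26 lower and 3 higher (4 higher and 20 lower adjusted over the list alone; mean log2 change -1.22, camera adjusted p = 5.50e-08). Interferon genes were higher in 25 of 36 cases and lower in 3 (25 higher and 3 lower adjusted over the list alone; mean log2 change 0.87, camera adjusted p = 2.88e-07, adjusted p = 0.0968 with an estimated correlation), and Irf7 rose by 2.47 on the log2 scale. Of 19 NRF2 genes 13 rose and 2 fell (15 higher and 2 lower adjusted over the list alone; mean log2 change 0.62, camera adjusted p = 0.000482). NF-kB and inflammatory cytokine genes were split, with 14 of 24 lower, such as Tnf (from 226 ± 15.2 to 29.8 ± 2.47 TPM), and 7 higher (7 higher and 14 lower adjusted over the list alone; mean log2 change -0.76, camera adjusted p = 0.0112, adjusted p = 0.240 with an estimated correlation). Genes of maturing granulocytes declined. Of 16 primary granule genes 11 fell and 1 rose (1 higher and 12 lower adjusted over the list alone; mean log2 change -0.53, camera adjusted p = 5.58e-06, adjusted p = 0.133 with an estimated correlation). The myeloperoxidase gene Mpo fell from 7877 ± 182 to 4307 ± 87.1 TPM. Of 21 neutrophil late granule genes 13 fell and 3 rose (3 higher and 13 lower adjusted over the list alone; mean log2 change -0.55, camera adjusted p = 0.000933, adjusted p = 0.295 with an estimated correlation). DNA replication genes had 14 of 35 lower and 2 higher (2 higher and 14 lower adjusted over the list alone; mean log2 change -0.26, camera adjusted p = 0.000482, adjusted p = 0.150 with an estimated correlation). The ligase gene Lig1 had a log2 change of -0.91. The spliceosome core had 20 of 39 genes higher and 1 lower (24 higher and 2 lower adjusted over the list alone; mean log2 change 0.24, camera adjusted p = 0.000442, adjusted p = 0.108 with an estimated correlation). In the exosome 11 of 16 genes were higher and 1 lower (12 higher and 1 lower adjusted over the list alone; mean log2 change 0.37, camera adjusted p = 0.00327, adjusted p = 0.133 with an estimated correlation). Of 18 cap binding genes 12 rose and 2 fell (12 higher and 2 lower adjusted over the list alone; mean log2 change 0.34, camera adjusted p = 0.00782, adjusted p = 0.0875 with an estimated correlation). In the heat shock list 13 of 17 rose and 3 fell (13 higher and 3 lower adjusted over the list alone; mean log2 change 0.34, camera adjusted p = 0.00148, adjusted p = 0.0795 with an estimated correlation). The HOXA and MEIS program had 12 of 22 genes lower and 5 higher (5 higher and 12 lower adjusted over the list alone; mean log2 change -0.29, camera adjusted p = 0.0138, adjusted p = 0.254 with an estimated correlation). For p53 targets, 12 of 27 rose and 7 fell without a call for the list (12 higher and 7 lower adjusted over the list alone; mean log2 change 0.17, camera adjusted p = 0.426). In the BCL2 family 5 of 14 rose, Bax and Bcl2l1 among them, and 5 fell (6 higher and 5 lower adjusted over the list alone; mean log2 change 0.78, camera adjusted p = 0.331). Unfolded protein genes of the endoplasmic reticulum had a mean change of -0.06 while their test pointed up (camera adjusted p = 0.972).

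At 10 h most of these lists in GMP still differed from before treatment. Idi1 stood at 119.8 ± 7.19 TPM and Mvd at 66.8 ± 1.82 TPM, and all 24 cholesterol genes were again higher than before treatment (24 higher adjusted over the list alone; mean log2 change 2.38, camera adjusted p = 1.06e-20). The chemokine gene Cxcl10 fell from 169 ± 6.06 to 2.17 ± 0.901 TPM (log2 change -5.79 ± 0.20, adjusted p = 6.64e-08 in limma) and Tnf fell from 226 to 19.4 TPM. Spint1, a protease inhibitor gene, rose from 0.0529 ± 0.0138 to 28.2 ± 2.05 TPM (log2 change 4.79 ± 0.09, adjusted p = 3.97e-09 in limma), and Tarm1 stayed high at 108 ± 4.52 TPM. Myc remained above its start, from 339 ± 12.2 to 698 ± 21.7 TPM (log2 change 1.04 ± 0.05, adjusted p = 3.86e-07 in limma), and Mpo fell from 7877 to 3273 TPM (log2 change -1.27 ± 0.06, adjusted p = 3.17e-07 in limma). Meis1 was lower (log2 change -0.36 ± 0.10, adjusted p = 0.0193 in limma), a call lost without some single samples and after quantile normalization, while Hoxa9 and Dcps did not pass (adjusted p = 0.115 and 0.271 in limma). Quantile normalization gave a call for Hoxa9 (adjusted p = 0.0219), and a fit of the 0 h and 10 h samples alone gave one for Dcps (adjusted p = 0.0386). Of 34 MYC and ribosome biogenesis genes 33 rose (33 higher adjusted over the list alone; mean log2 change 0.88, camera adjusted p = 4.27e-18). In the ATF4 list 28 of 36 rose and 5 fell (29 higher and 6 lower adjusted over the list alone; mean log2 change 0.60, camera adjusted p = 2.53e-07). Immediate early genes had 21 of 26 lower and 3 higher (3 higher and 21 lower adjusted over the list alone; mean log2 change -1.57, camera adjusted p = 1.41e-09). NF-kB genes had 16 of 24 lower and 3 higher (3 higher and 16 lower adjusted over the list alone; mean log2 change -1.29, camera adjusted p = 1.64e-06, adjusted p = 0.0508 with an estimated correlation). The spliceosome core had 28 of 39 genes higher and none lower (29 higher adjusted over the list alone; mean log2 change 0.34, camera adjusted p = 1.33e-06). Prpf31 rose by 1.04 on the log2 scale. Cap binding genes were higher in 10 of 18 cases and lower in 1 (12 higher and 1 lower adjusted over the list alone; mean log2 change 0.39, camera adjusted p = 0.00114). The exosome had 13 of 16 genes higher and 1 lower (13 higher and 1 lower adjusted over the list alone; mean log2 change 0.54, camera adjusted p = 4.95e-05, adjusted p = 0.0519 with an estimated correlation). Of 19 NRF2 genes 15 rose and 2 fell (17 higher and 2 lower adjusted over the list alone; mean log2 change 0.70, camera adjusted p = 1.22e-05). Among falling lists, primary granule genes had 11 of 16 lower and 3 higher (3 higher and 12 lower adjusted over the list alone; mean log2 change -0.59, camera adjusted p = 4.95e-05, adjusted p = 0.165 with an estimated correlation). The HOXA and MEIS program had 15 of 22 lower and 4 higher (4 higher and 15 lower adjusted over the list alone; mean log2 change -0.44, camera adjusted p = 0.000887, adjusted p = 0.130 with an estimated correlation). Mast cell, basophil and eosinophil markers had 9 of 14 lower and 3 higher (3 higher and 9 lower adjusted over the list alone; mean log2 change -0.53, camera adjusted p = 0.0141, adjusted p = 0.299 with an estimated correlation). B cell markers were lower in 8 of 12 cases (9 lower adjusted over the list alone; mean log2 change -0.82, camera adjusted p = 0.00137, adjusted p = 0.0684 with an estimated correlation). Mitochondrially encoded transcripts had 5 of 13 lower and lost their call after median centring (5 lower adjusted over the list alone; mean log2 change -0.31, camera adjusted p = 0.0390, adjusted p = 0.491 with an estimated correlation). The interferon list no longer passed, with 11 of 36 higher and 4 lower (11 higher and 4 lower adjusted over the list alone; mean log2 change 0.17, camera adjusted p = 0.199). The limma test called 3374 of 14246 genes higher and 3057 lower.

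Between 6 h and 10 h the interferon and inflammatory genes of GMP fell while replication genes rose. Cxcl10 fell from 34.5 ± 5.64 to 2.17 ± 0.901 TPM and the antiviral gene Oasl1 fell from 10.5 to 1.45 TPM (log2 change -3.51 ± 0.20 and -2.22 ± 0.13, adjusted p = 7.06e-05 and 7.06e-05 in limma). Myc came down from 1021 to 698 TPM (log2 change -0.55 ± 0.05, adjusted p = 0.000697 in limma). Of 35 DNA replication genes 19 rose, E2f2 and Ccne2 among them, and none fell (28 higher adjusted over the list alone; mean log2 change 0.36, camera adjusted p = 1.74e-20). Histones had 14 of 28 members higher (17 higher adjusted over the list alone; mean log2 change 0.32, camera adjusted p = 2.33e-14, adjusted p = 0.0877 with an estimated correlation). Interferon genes were lower in 20 of 36 cases and higher in 2 (2 higher and 23 lower adjusted over the list alone; mean log2 change -0.71, camera adjusted p = 1.71e-11, adjusted p = 0.0616 with an estimated correlation). NF-kB genes fell in 13 of 24 cases (18 lower adjusted over the list alone; mean log2 change -0.52, camera adjusted p = 2.00e-10). Of 26 immediate early genes 9 fell (1 higher and 11 lower adjusted over the list alone; mean log2 change -0.35, camera adjusted p = 4.74e-05, adjusted p = 0.0616 with an estimated correlation). Cholesterol genes went on rising, 12 of 24 higher and 1 lower (15 higher and 1 lower adjusted over the list alone; mean log2 change 0.41, camera adjusted p = 1.62e-11). Ribosomal protein genes had 1 of 43 higher (6 higher adjusted over the list alone; mean log2 change 0.12, camera adjusted p = 4.77e-07, adjusted p = 0.251 with an estimated correlation). Of 29 G2/M and mitosis genes 4 fell (9 lower adjusted over the list alone; mean log2 change -0.13, camera adjusted p = 0.00154, adjusted p = 0.0877 with an estimated correlation). The limma test called 457 of 14246 genes higher and 552 lower. Leaving out 1 sample gave 371 to 573 called genes, and no filter on low values gave 639. The split turned to 714 higher and 382 lower when changes were centred on the median gene.

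**Figure D1:**
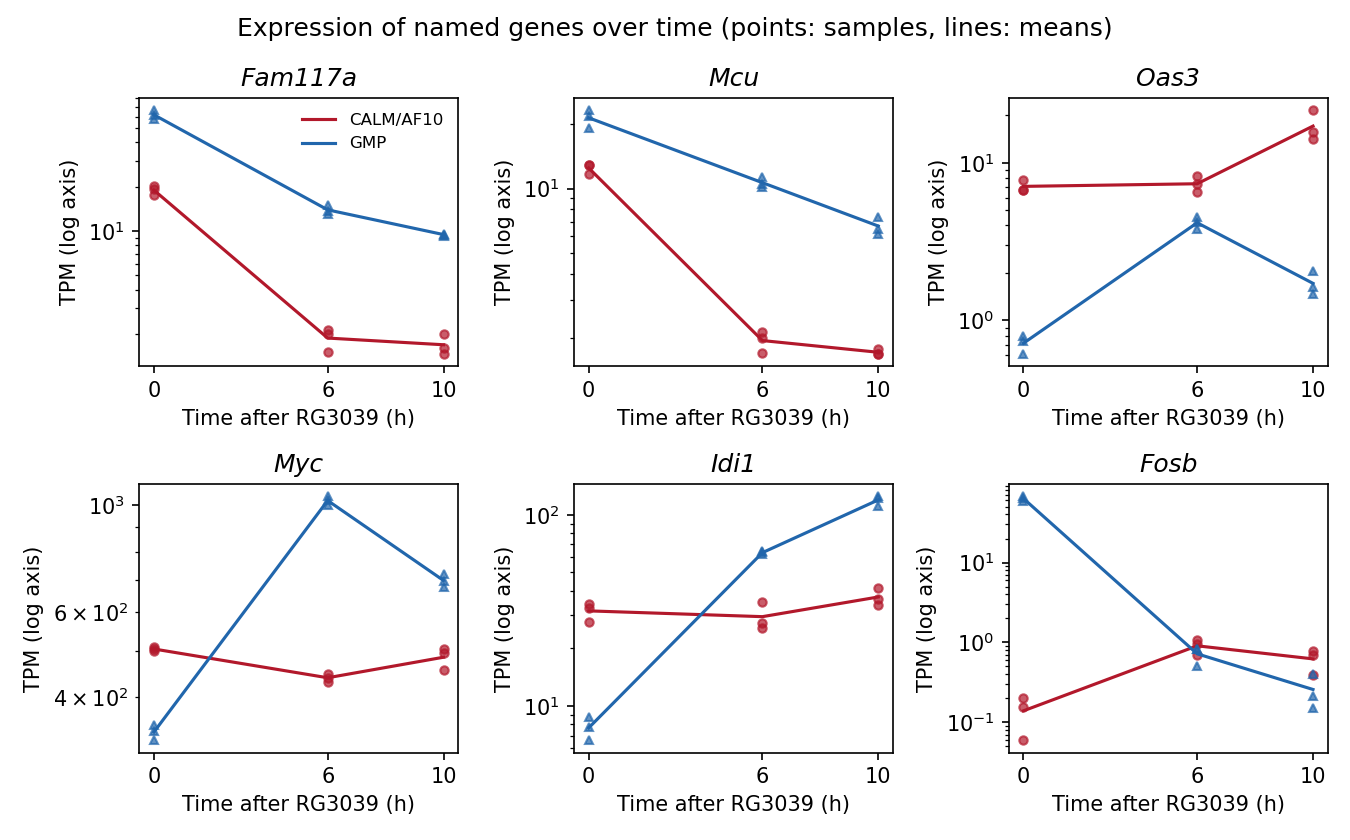
TPM of Fam117a, Mcu, Oas3, Myc, Idi1 and Fosb (log axis) at 0, 6 and 10 h of RG3039 in CALM/AF10 cells and GMP, with 1 point per sample (n = 3 per group) and a line through the group means. Fam117a and Mcu were lower after treatment in both cell types, Idi1 rose and Fosb fell in GMP, and levels are not compared between the cell types because their tables list different genes.

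The next comparison took the difference of the changes in leukemia cells and GMP, where effects of culture or handling need not cancel. At 6 h large differences came from stimulation genes that fell steeply in GMP and were uncalled or below the filter in CALM/AF10 cells. The log2 change of Fosb was higher in CALM/AF10 cells by 5.97 ± 0.18, that of Cxcl2 by 5.11 ± 0.27 and that of Dusp1 by 4.37 ± 0.15 (adjusted p = 1.26e-12 to 1.07e-09 in limma). Fosb started at 0.139 ± 0.0732 TPM in CALM/AF10 cells, so it had little room to fall there. Genes that rose in GMP gave large negative differences, such as -5.37 ± 0.14 for Lpl, -5.25 ± 0.10 for Tarm1 and -4.37 ± 0.45 for Ccl5 (adjusted p = 2.33e-14 to 1.96e-06 in limma). Tarm1 was already at 877 ± 34.4 TPM in CALM/AF10 cells before treatment and at 878 ± 4.22 TPM at 6 h. Myc differed by -1.78 ± 0.06 at 6 h and -1.10 ± 0.06 at 10 h (adjusted p = 4.46e-12 and 1.07e-09 in limma). Dcps, Hoxa9 and Meis1 did not differ at an adjusted p under 0.05 at either time, with adjusted p = 0.225 to 0.577 at 6 h and 0.199 to 0.744 at 10 h in limma. For Dcps at 6 h this rested on a single GMP sample, without which it differed by 0.42 (adjusted p = 0.00425 in limma). Of 14044 genes in both tables, limma found 2279 with a higher and 3123 with a lower change in CALM/AF10 cells at 6 h, and 2597 and 2842 at 10 h.

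Cholesterol biosynthesis separated the cell types, since all 24 genes had a lower change in CALM/AF10 cells at both times. At 6 h the list differed with 24 lower adjusted over the list alone (mean log2 change -2.04, camera adjusted p = 1.12e-23), and at 10 h it differed by a mean of -2.17 (camera adjusted p = 8.36e-26). MYC and ribosome biogenesis genes had a lower change in 32 of 34 cases at 6 h (33 lower adjusted over the list alone; mean log2 change -1.02, camera adjusted p = 2.33e-21). They did so in all 34 cases at 10 h (mean log2 change -0.90, camera adjusted p = 2.09e-20). The ATF4 list was lower in 29 of 38 cases and higher in 5 at 6 h (5 higher and 31 lower adjusted over the list alone; mean log2 change -0.71, camera adjusted p = 1.35e-09). It was lower in 31 at 10 h (mean log2 change -0.90, camera adjusted p = 1.73e-13). Immediate early genes had a higher change in CALM/AF10 cells in 19 of 26 cases and a lower one in 3 at 6 h (20 higher and 3 lower adjusted over the list alone; mean log2 change 1.28, camera adjusted p = 5.10e-11). Of 37 interferon genes at 6 h 22 had a lower change in CALM/AF10 cells and 2 a higher one (2 higher and 22 lower adjusted over the list alone; mean log2 change -0.84, camera adjusted p = 5.16e-06, adjusted p = 0.303 with an estimated correlation). At 10 h 18 were higher and 7 lower (20 higher and 7 lower adjusted over the list alone; mean log2 change 0.43, camera adjusted p = 0.0531). The list passed at 10 h only after median centring (camera adjusted p = 0.0447). NRF2 genes were lower in 13 of 19 cases and higher in 2 at 6 h (2 higher and 14 lower adjusted over the list alone; mean log2 change -0.66, camera adjusted p = 0.000682). Cap binding genes were lower in 12 of 18 (1 higher and 12 lower adjusted over the list alone; mean log2 change -0.45, camera adjusted p = 0.00190). At 10 h histones were lower in 14 of 28 cases (14 lower adjusted over the list alone; mean log2 change -0.33, camera adjusted p = 0.000226, adjusted p = 0.325 with an estimated correlation). NF-kB genes were higher in 17 of 24 cases and lower in 2 (17 higher and 2 lower adjusted over the list alone; mean log2 change 1.36, camera adjusted p = 1.19e-07). At 10 h ribosomal protein genes had a mean difference of 0.06 while their test pointed down (camera adjusted p = 0.303).

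**Figure D2:**
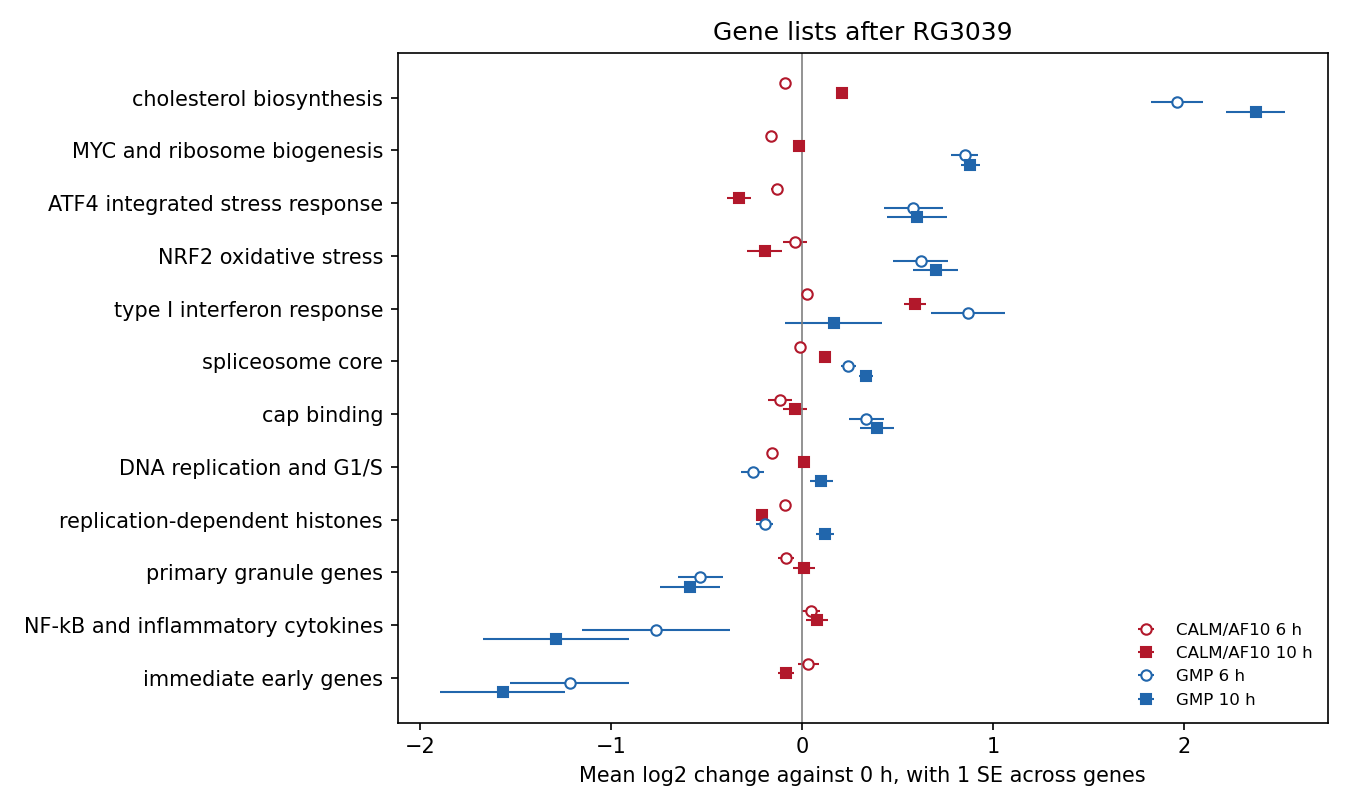
Mean log2 change of 12 gene lists at 6 h and 10 h against 0 h in CALM/AF10 cells and in GMP (bars: 1 standard error across the genes of a list, which are not independent replicates). The cholesterol list stands at 1.96 and 2.38 in GMP and the interferon list at 0.03 and 0.59 in CALM/AF10 cells.

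Part of the response was common to both times and both cell types. In CALM/AF10 cells 546 genes were higher and 628 lower at both 6 h and 10 h, where independent lists would share 73.4 and 79.0, and 5 went opposite ways. In GMP 2713 were higher and 2192 lower at both times (812 and 609 for independent lists), and 23 went opposite ways. Both times were compared with the same 0 h samples, which alone makes their changes correlate. The covariance of the 6 h and 10 h changes across genes was 0.0776 in CALM/AF10 cells against 0.0102 for simulated unchanged groups, and 0.359 against 0.0191 in GMP. The 0 h samples were too few to split, so part of the overlap may come from them. Across cell types, which share no samples, 278 of 11672 genes rose in both at 6 h (166 for independent lists, Fisher's exact test, p = 3.37e-23), 316 fell in both (176) and 266 went opposite ways (355). At 10 h 575 rose in both (338), 376 fell in both (219) and 388 went opposite ways (545). The correlation of changes across genes, which are not independent replicates, was 0.143 at 6 h and 0.189 at 10 h.

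Untreated levels of Hoxa9, Meis1, Dcps and Myc are given side by side without a test, because the tables of the cell types list different genes and their levels may not be comparable. CALM/AF10 cells held 186.9 ± 7.45 TPM of Hoxa9 against 35.0 ± 1.52 in GMP, 42.2 ± 1.49 TPM of Meis1 against 8.18 ± 0.511, and 15.4 ± 1.13 TPM of Dcps against 45.0 ± 2.73. Myc stood at 504 ± 5.18 TPM in CALM/AF10 cells and 339 ± 12.2 TPM in GMP. Some ribosomal protein levels differed in ways that point to the tables, such as 0.0807 ± 0.105 against 234 ± 58.8 TPM of Rps12.

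The AML lines asked which genes tell MLL/AF9 from CALM/AF10 leukemia, with 2 lines for each fusion as the replicates. Late granule genes and the cytokine gene Il1b were lower in the MLL/AF9 lines, Fcnb at 24.97 TPM against 500.0, Padi4 at 7.11 against 158, Mmp9 at 60.0 against 1566 and Il1b at 4.05 against 78.5 (means of 2 lines). Meis1, a partner of HOX proteins, was lower in MLL/AF9 lines, at 14.0 against 52.2 TPM (log2 change -2.55 ± 0.35, adjusted p = 0.0200 in edgeR). Erg was lower at 0.393 against 14.3 TPM (log2 change -5.83 ± 0.47, adjusted p = 0.00789 in edgeR). The eosinophil gene Prg2 was lower as well (log2 change -5.66 ± 0.58, adjusted p = 0.0102 in edgeR). Tcf4 was higher, at 214 against 21.04 TPM (log2 change 2.55 ± 0.32, adjusted p = 0.0171 in edgeR), a call lost without either CALM/AF10 line, and so was Stra6 (log2 change 6.98 ± 0.62, adjusted p = 0.00789 in edgeR). Fcnb, Padi4, Mmp9 and Il1b had log2 differences of -5.03, -5.12, -5.04 and -5.05 with adjusted p = 0.00789 to 0.0128 in edgeR. The folds that edgeR fitted to scaled counts differed from the ratios of the TPM means by more than 1.5 times for Fcnb, Padi4, Il1b, Meis1, Erg and Tcf4. Hoxa9, Myc and Dcps did not pass (adjusted p = 0.638, 0.827 and 0.848 in edgeR), though Hoxa9 and Myc did when all 12 samples counted as independent. Neutrophil late granule genes were lower in 13 of 21 cases and higher in none (1 higher and 20 lower adjusted over the list alone; mean log2 change -3.87, camera adjusted p = 2.66e-49, adjusted p = 0.705 with an estimated correlation). Mast cell, basophil and eosinophil markers were lower in 2 of 14 (7 lower adjusted over the list alone; mean log2 change -2.05, camera adjusted p = 4.38e-07, adjusted p = 0.705 with an estimated correlation). Stem and progenitor genes were lower in 2 of 17 (5 lower adjusted over the list alone; mean log2 change -0.997, camera adjusted p = 0.000608, adjusted p = 0.705 with an estimated correlation). Dendritic cell markers were lower in 3 of 15 and higher in 1 (1 higher and 9 lower adjusted over the list alone; mean log2 change -1.88, camera adjusted p = 0.000608, adjusted p = 0.859 with an estimated correlation). Megakaryocyte markers were lower in 2 of 8 (2 lower adjusted over the list alone; mean log2 change -1.80, camera adjusted p = 0.000608, adjusted p = 0.859 with an estimated correlation). None of 34 MYC and ribosome biogenesis genes passed singly, while the list was higher in MLL/AF9 lines (0 adjusted over the list alone; mean log2 change 0.75, camera adjusted p = 4.38e-07, adjusted p = 0.859 with an estimated correlation). No list kept its call with an estimated correlation. Of 15287 genes, edgeR called 139 higher and 325 lower in MLL/AF9 lines. With 2 lines per fusion this count was unstable, rising to 2358 without MLL/AF9 line 1 and 1129 without MLL/AF9 line 2. It was 1445 with DESeq2. Scaling by library size without TMM gave 207 higher and 222 lower and set the median of all genes at 0.424, and limma on log2(TPM + 1) gave 271 and 179 with the median at 0.470.

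The 2 CALM/AF10 lines differed in stimulation, red cell and mitochondrial transcripts. Line 2 held less Fosb than line 1 (3.83 ± 0.332 against 63.3 ± 1.42 TPM), less Egr1 (5.08 against 112) and less of the beta globin gene Hbb-bt (87.8 against 736), and more Irf8, a monocyte fate factor (138 ± 3.32 against 26.8 ± 9.32). In edgeR these genes differed by -4.27, -4.63, -3.23 and 1.80 with adjusted p = 4.90e-16 to 1.34e-12. Hoxa9, Meis1, Myc and Dcps did not pass (adjusted p = 0.0573 to 1.00 in edgeR), but for Hoxa9, Meis1 and Myc this depended on the settings. Hoxa9 was called higher in line 2 with no filter on low values, with library size scaling, with DESeq2 size factors, with DESeq2, with limma, and in 5 of 6 fits that left out 1 sample. Meis1 was called higher with 4 of these 5 settings and in 2 of the 6 fits, and Myc only with no filter. Immediate early genes were lower in 19 of 26 cases and higher in 1 (1 higher and 20 lower adjusted over the list alone; mean log2 change -1.41, camera adjusted p = 2.64e-54). Erythroid markers were lower in 12 of 14 (13 lower adjusted over the list alone; mean log2 change -2.10, camera adjusted p = 8.09e-30). Mitochondrially encoded transcripts were lower in all 13 cases (13 lower adjusted over the list alone; mean log2 change -1.17, camera adjusted p = 6.96e-33). B cell markers were lower in 10 of 14 (11 lower adjusted over the list alone; mean log2 change -1.44, camera adjusted p = 2.87e-07). Monocyte and macrophage genes were higher in 18 of 27 and lower in 7 (18 higher and 8 lower adjusted over the list alone; mean log2 change 0.21, camera adjusted p = 4.57e-17). The edgeR test called 2130 of 15287 genes higher and 2193 lower in line 2, and library size scaling gave 2791 and 1902.

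MLL/AF9 line 2 held more stimulation and stromal transcripts than line 1 and fewer histone and ribosomal protein transcripts. Egr1 stood at 258 ± 13.6 TPM in line 2 against 1.81 ± 0.555 in line 1, Jun at 256 against 5.92, Cxcl2 at 116 against 0.123 and the collagen gene Col1a1 at 38.1 against 1.00. Lower in line 2 were Ly6c2, a monocyte surface gene, at 1589 against 5354 TPM, the elastase gene Elane at 2817 against 5397, and the ribosomal protein gene Rps7 at 463 against 1033. In edgeR the log2 differences were 6.77, 5.06, 8.08 and 5.08 for the higher genes and -2.15, -1.32 and -1.54 for the lower ones, with adjusted p = 4.46e-18 to 1.99e-13. For Cxcl2, near 0 in line 1, the fitted fold was smaller than the ratio of the TPM means. Meis1 was higher in line 2 (log2 change 0.45 ± 0.08, adjusted p = 6.46e-05 in edgeR). Histones were lower in 27 of 28 cases (27 lower adjusted over the list alone; mean log2 change -2.08, camera adjusted p = 5.64e-69). Ribosomal proteins were lower in 42 of 43 (42 lower adjusted over the list alone; mean log2 change -1.35, camera adjusted p = 2.09e-49). Immediate early genes were higher in 22 of 26 and lower in 2 (22 higher and 2 lower adjusted over the list alone; mean log2 change 2.36, camera adjusted p = 1.61e-39). Stromal and endothelial markers were higher in 12 of 14 and lower in 1 (12 higher and 1 lower adjusted over the list alone; mean log2 change 2.43, camera adjusted p = 2.20e-12). Mitochondrially encoded transcripts were higher in 10 of 13 (10 higher adjusted over the list alone; mean log2 change 0.63, camera adjusted p = 4.88e-06). Primary granule genes were lower in 14 of 16 and higher in 1 (1 higher and 14 lower adjusted over the list alone; mean log2 change -0.82, camera adjusted p = 8.54e-10). G2/M and mitosis genes were lower in 20 of 29 and higher in 3 (3 higher and 20 lower adjusted over the list alone; mean log2 change -0.61, camera adjusted p = 1.40e-05). The monocyte list had a mean difference of 0.35 while its test pointed down (camera adjusted p = 0.0788). T and NK cell markers, with 14 genes tested, 5 higher and 0 lower, did not pass (5 higher adjusted over the list alone; mean log2 change 0.95, camera adjusted p = 0.148). Nor did the 16 nonsense-mediated decay genes, with 6 higher and 6 lower (6 higher and 6 lower adjusted over the list alone; mean log2 change -0.26, camera adjusted p = 0.770). The HOXB list had 3 genes tested, of which 2 were higher, and was too short for a list test. The edgeR test called 4483 of 15287 genes higher and 4549 lower in line 2. Library size scaling gave 5780 and 3434 and set the median of all genes at 0.266.

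**Figure D3:**
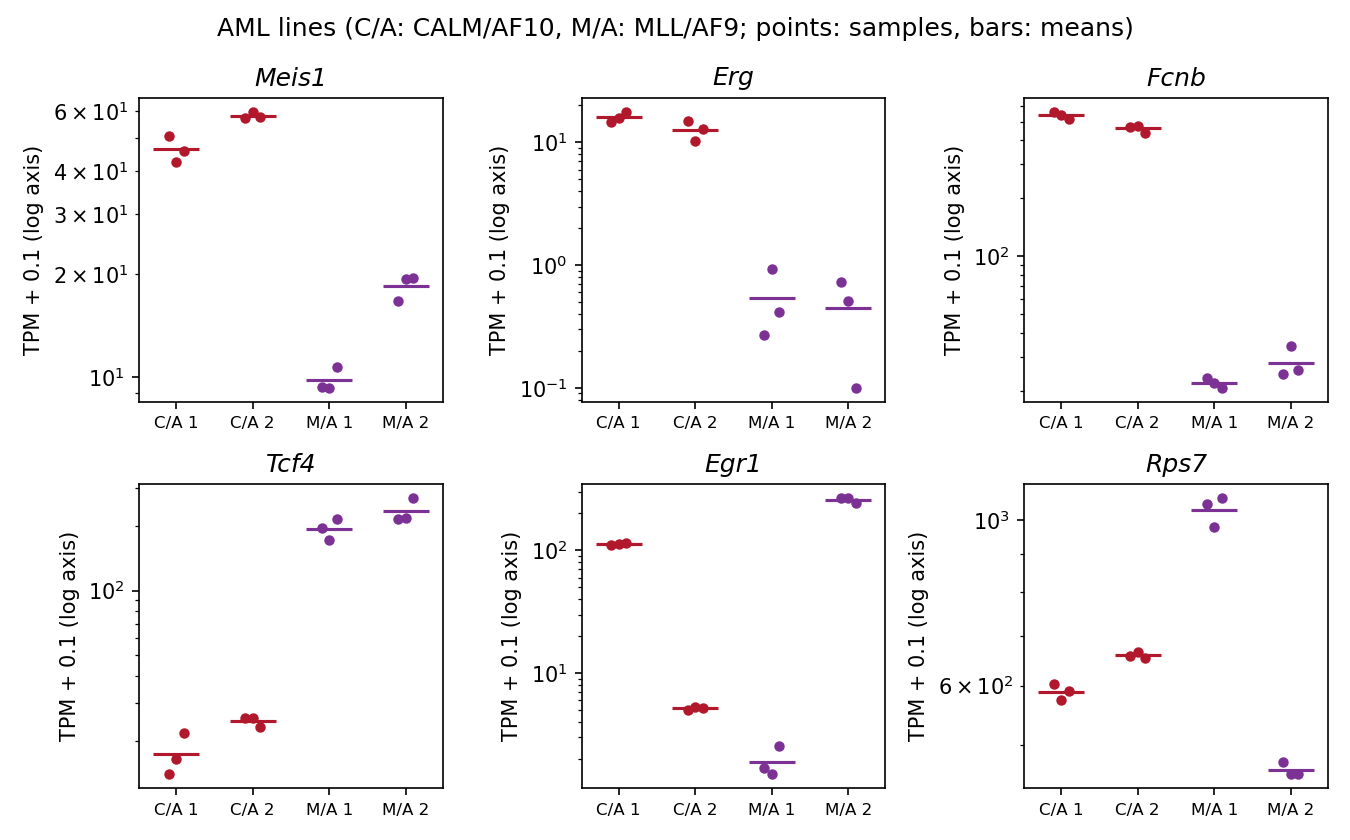
TPM of Meis1, Erg, Fcnb, Tcf4, Egr1 and Rps7 (log axis of TPM + 0.1) in CALM/AF10 lines 1 and 2 and MLL/AF9 lines 1 and 2, with 1 point per sample (n = 3 per line) and a bar at the mean. Fcnb and Erg were lower in both MLL/AF9 lines, and Egr1 differed between the lines of each fusion.

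The deposited comparison tables list splice junctions that gained use after RG3039, which asks how Dcps inhibition changes splicing. Splicing regulators were prominent among the genes with a listed junction, in a comparison that did not match the number of introns. In GMP 13 of 38 SR and hnRNP genes had one at 6 h and 16 at 10 h, where expression-matched random genes gave 2.30 and 3.03 (adjusted permutation p = 0.0033 at both times), and in CALM/AF10 cells 10 of 38 at 6 h against 2.48 (adjusted permutation p = 0.003). At 10 h in CALM/AF10 cells it was 8 of 38 against 3.56, which was not a call (adjusted permutation p = 0.384). The unadjusted p of the 3 tests that passed was 1e-04, the smallest that 10000 random lists can give. Primary granule genes had a junction in 7 of 16 cases in GMP at both times (adjusted permutation p = 0.0033 and 0.01155). All listed junctions have the authors' q under 0.05 and a positive log2 ratio, so losses of use are not in the tables. The tables hold 486 junctions at 6 h and 689 at 10 h for CALM/AF10 cells and 291 and 400 for GMP. In 40.3, 40.5, 40.5 and 39.2 percent of them the event was an alternative 5' splice site, and in 22.0, 15.4, 14.1 and 14.0 percent a retained intron. Junctions outside the annotation the authors used made up 64.2 and 59.1 percent in CALM/AF10 cells and 40.9 and 37.8 percent in GMP. The 6 h and 10 h tables shared 304 junctions in CALM/AF10 cells and 145 in GMP, while the cell types shared 31 at 6 h and 46 at 10 h.

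Several of the strongest junctions of CALM/AF10 cells lay in genes whose expression fell. An alternative 3' splice site of Mcu (mm10 chromosome 10, 59517678 to 59616523) went from 1 to 31 percent spliced in (PSI) at 6 h, and an alternative 5' splice site of Fam117a (chromosome 11, 95354556 to 95363998) from 0 to 40 percent at 10 h. Their mean raw counts after treatment were only 8 and 4. In Srrt an alternative 5' splice site (chromosome 5, 137300414 to 137301317) went from 15 to 60 percent at 6 h and stood at 43 percent at 10 h. The kinase scaffold gene Ksr1 gained an alternative 5' splice site, from 1 to 39 percent at 6 h, and the ceramide kinase gene Cerk an alternative 3' splice site, from 1 to 42 percent at 10 h. The authors predicted each of these 5 junctions to lead to decay. In GMP an alternative 5' splice site of Tiam1, an activator of RAC signalling, went from 0 to 37 percent at 6 h and 31 percent at 10 h. Splicing regulators shifted too. A junction that skips an exon of Tra2b went from 48 to 71 and 73 percent, and a retained intron of Srsf2 from 66 to 89 and 86 percent. Hnrnpd gained the same exon junction in both cell types, from 57 to 75 percent in GMP and from 63 to 73 percent in CALM/AF10 cells at 6 h (chromosome 5, 99976591 to 99978391). The q-value of each of these junctions is printed as 0, and the PSI values are group means that the tables give without a spread.

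Genes with a listed junction were not called as a group by camera, which tests for a shift in 1 direction. Their median log2 change was -0.01 at 6 h and 0.07 at 10 h in CALM/AF10 cells and 0.05 and 0.06 in GMP (limma's camera test, adjusted p = 0.873, 0.299, 0.299 and 0.348). Among random genes matched on expression, these medians stood at percentiles 84.5, 99.98, 36.6 and 1.24, so only the 10 h medians lay outside the middle 95 percent, high in CALM/AF10 cells and low in GMP. Genes with a junction that the authors predicted to lead to decay fell relative to the other genes with a junction. At 10 h the difference of mean log2 changes was -0.12 in CALM/AF10 cells (142 against 352 genes, two-sided permutation test, p = 0.00711, adjusted p = 0.0142) and -0.42 in GMP (45 against 250 genes, p = 0.00015, adjusted p = 6e-04). At 6 h it was -0.09 in CALM/AF10 cells (adjusted p = 0.1195) and -0.08 in GMP (permutation p = 0.457).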

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

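Chosen only after the result was seen were the tests of scaling for interferon and immediate early genes and the test of handling in GMP. The results below were picked out because the change over time differed between CALM/AF10 cells and GMP in a direct test. The groups of 3 samples are too small for a test of single outlying samples.

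The change differed for 5402 genes at 6 h and 5439 genes at 10 h in limma. Among the lists that differed, values are mean log2 differences (change in CALM/AF10 cells minus change in GMP). Cholesterol biosynthesis differed by -2.04 at 6 h and -2.17 at 10 h, and MYC and ribosome biogenesis by -1.02 and -0.90. The ATF4 list differed by -0.71 and -0.90, NRF2 by -0.66 and -0.88, cap binding by -0.45 and -0.43, the exosome by -0.43 and -0.45 and the spliceosome core by -0.25 and -0.21. Heat shock genes differed by -0.46 and -0.0297, the second value being a mean over members that went both ways. In the other direction immediate early genes differed by 1.28 and 1.52, NF-kB and inflammatory cytokines by 0.81 and 1.36, primary granule genes by 0.45 and 0.60, and neutrophil late granule genes by 0.44 and 0.49. The HOXA and MEIS program differed by 0.25 and 0.38, mast cell, basophil and eosinophil markers by 0.36 and 0.52, and B cell markers by 0.38 and 0.75. At 6 h alone the interferon list differed by -0.84. At 10 h alone histones differed by -0.33 and erythroid markers by 0.60. With an estimated correlation 7 of the 16 lists at 6 h and 10 of the 17 at 10 h passed. At both times these were cholesterol, MYC, ATF4, NRF2, cap binding, exosome and immediate early genes, joined at 10 h by NF-kB, HOXA and MEIS and B cell genes, and the other lists lost their call.

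Single genes followed the same lines. Fosb differed by 5.97 and 6.19 at 6 h and 10 h, Cxcl2 by 5.11 and 4.95 and Dusp1 by 4.37 and 5.08. Lpl differed by -5.37 and -5.29, Tarm1 by -5.25 and -4.98 and Myc by -1.78 and -1.10. Ccl5 differed by -4.37 at 6 h.

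Splits of the samples show how far chance can be excluded for these counts. For the differences, 2 of 100 splits gave as many called genes at each time, the real one included. The other split that reached as many gave 5885 genes at 6 h and 6353 at 10 h. It exchanges treated and untreated samples of a single cell type, which tests the sum of the changes and not their difference. Most splits mix treated and untreated samples within a cell type and so break up the changes over time themselves. The median apart from the real split was 0 genes, so these splits cannot exclude chance for the difference between the cell types. For the comparisons of 3 against 3 samples there are 10 splits, too few for a share under 0.05. The real split was the 1 that gave the most genes each time, 1612 against at most 1 in CALM/AF10 cells at 6 h, 2456 against 0 at 10 h and 376 against at most 1 from 6 h to 10 h. In GMP it gave 6268 against at most 1, 6431 against 0 and 1009 against at most 4. Between the CALM/AF10 lines it gave 4323 against at most 1, and between the MLL/AF9 lines 9032 against 0. MLL/AF9 against CALM/AF10 lines has only 3 splits, with 464 genes for the real one and 0 for the others.

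Interferon genes rose between 6 h and 10 h in CALM/AF10 cells, by a mean of 0.57 on the log2 scale, while they fell by 0.71 in GMP, but only 9 of 37 members passed in CALM/AF10 cells and neither list kept its call with an estimated correlation (adjusted p = 0.210 and 0.0616 in limma). If a shift common to all genes of a sample were the cause, median centring would remove the rise. The mean stayed at 0.524 ± 0.053 (SE across genes), which argues against such a shift but not against other forms of scaling. The monocyte and dendritic lists had mean changes of 0.0647 ± 0.0366 and 0.0184 ± 0.077, but their genes already stood at medians of 47.3 and 38.0 TPM in the leukemia cells at 6 h, so the planned test would miss a small share of other cells and cannot exclude them. Other cells and time in culture stay open, the latter because there were no untreated samples at 10 h.

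Immediate early genes fell in GMP by 6 h, 19 of 26 of them, while 13 of 17 heat shock genes rose. If a difference between samples in the distribution of all values were the cause of the fall, quantile normalization would remove it. The immediate early genes stayed at a mean of -1.248 ± 0.318, which argues against such a difference. The test was chosen with the list mean of -1.216 already seen, so this outcome could be foreseen. Cell sorting or handling before the 0 h sample may have raised the immediate early genes at the start, though not the heat shock genes that were lower then. The immediate early list went on falling from 6 h to 10 h, by -0.3517 ± 0.099, which is less than its fall to 6 h, and without untreated samples at 6 h and 10 h handling and the drug cannot be told apart.

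Stromal, immediate early and mitochondrial transcripts were higher and histone and ribosomal protein transcripts lower in MLL/AF9 line 2 than in line 1. Cells of other types in general would raise all their markers, but those of mast cells, basophils and eosinophils had a mean difference of -0.3152 ± 0.361 while stromal markers had 2.43 ± 0.453. Megakaryocyte markers (1.02 ± 0.264) and T and NK cell markers (0.954 ± 0.313) had positive means without a call for either list, and an admixture of those or of stromal cells stays open. When every library was thinned to the same size, 94.57 percent of called genes kept their call and direction, which argues against library size. Taking off a trend with gene length left ribosomal proteins at -1.031 ± 0.049 and histones at -1.72 ± 0.122, which argues against gene length as the whole cause.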

How the results depend on the processing

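Chosen only after the data were seen were scaling by library size without TMM, limma on TPM of the lines, DESeq2, leaving out whole lines, and the overlaps of calls under each setting. All other alternatives were planned. Of 260 alternative values of the counts, overlaps, junction numbers and junction expression tests, 227 stayed within 1.5 times the reported value or on the same side of the threshold. Of 142 values of named genes 119 kept their direction and call under all alternatives, and 19 changed their call in at least 1, mostly without a single sample. Lists kept their direction in all 280 alternative tests, of which 107 ended a call and 4 gave one.

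For CALM/AF10 cells from 6 h to 10 h, 376 called genes became 188 without the filter on low values and 140 with only the 2 groups fitted, and 64 to 263 without single samples. For GMP from 6 h to 10 h, 1009 became 639 without the filter and 371 to 573 without single samples. For MLL/AF9 against CALM/AF10 lines, 464 became 1228 without the filter, 1892 with line as a random effect and 1445 with DESeq2, and 409 to 2358 when a sample or a line was left out. It was 2358 without MLL/AF9 line 1 and 1129 without MLL/AF9 line 2, where the lone line of a fusion is assumed to vary like the others. Taking all 12 line samples as independent gave 8797, because the samples of a line then count as replicates of the fusion. Fewer samples or more genes tested can lower such counts, yet some rose, and the cause was not tested.

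Median centring turned the 697 higher and 915 lower genes of CALM/AF10 cells at 6 h into 1031 and 731. It turned the 280 and 96 from 6 h to 10 h into 194 and 153, where quantile normalization gave 119 and 154. In GMP from 6 h to 10 h it turned 457 and 552 into 714 and 382. For the CALM/AF10 lines the 2130 higher and 2193 lower genes became 3925 and 2030 without the filter, 2791 and 1902 with library size scaling, and 2370 and 965 with limma, which set the median of all genes at 0.115. For the MLL/AF9 lines 4483 and 4549 became 5780 and 3434 with library size scaling and 6445 and 2254 with limma (median of all genes 0.416), and the median was 0.206 without the filter. The cause was not tested.

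With an estimated correlation fewer lists passed. In CALM/AF10 cells 6, 5 and 16 lists at 6 h, at 10 h and from 6 h to 10 h became 0, 0 and 1, and in GMP 17, 17 and 18 became 5, 7 and 3. For the difference 16 and 17 lists became 7 and 10, and for the fusions 14 became 0. Median centring left 3 of the 6 in CALM/AF10 cells at 6 h. Counting a gene as shared in place of a junction gave 50 for 31 at 6 h and 82 for 46 at 10 h between the cell types.

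The values that changed sign were all of genes that did not pass in the reported fits. Dcps between the CALM/AF10 lines went to -0.0491 with a minimum of 5 TPM, to -0.0255 with 2 groups fitted and to -0.0633 to 0.190 without single samples. In GMP at 6 h Dcps ranged from -0.239 (adjusted p = 0.0332 in limma, a call) to 0.0703 and Meis1 from -0.0860 to 0.0628 without single samples. Dcps between the fusions was 0.168 with library size scaling and 0.412 with limma. The 10 h difference of Hoxa9 was 0.00332 after quantile normalization. The cause was not tested.

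No paired analysis was possible for the time course because its columns carry no replicate numbers, so the planned replicate block was not run there. In the lines the samples share only a number, since deviations of same-numbered samples correlated at -0.0475 to 0.0415. The replicate block gave 4060 called genes between the CALM/AF10 lines, 8830 between the MLL/AF9 lines and, in the fit of all 12 samples, 8641 between the fusions. The pseudocount, median centring and quantile normalization were not run on the lines, whose counts were fitted by edgeR. The depth of the time course is unknown, so its low genes are limited only by the TPM filter.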

Other observations

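The tests of shared responses and of decay below were planned before their results were seen, and Fam117a, Mcu and the sex-linked genes were singled out after their values were seen.

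Fam117a and Mcu, among the steepest falls in CALM/AF10 cells, were lower in GMP as well. In limma the log2 change of Fam117a in GMP was -2.07 at 6 h and -2.58 at 10 h (adjusted p = 1.055e-07 and 2.69e-08), and that of Mcu -0.94 and -1.55 (adjusted p = 7.12e-05 and 3.11e-06). A response shared by both cell types was tested on all genes at 6 h. It would need more genes to rise in both than independent lists give, and 278 did against 166. Fewer genes went opposite ways than independent lists give, 266 against 355. The 278 are a small share of the 3095 genes higher in GMP.

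Genes with a listed junction were shared too. At 10 h 75 genes had a listed junction in both cell types, where genes matched on expression gave 27.1 on average and 45 at most in 10000 draws (permutation p = 1e-04, the smallest they can give). At 6 h it was 49 against 14.3. A splicing response common to both cell types would give this, but identical junctions were few. They numbered 46 of 689 in CALM/AF10 cells and 400 in GMP at 10 h, and 31 of 486 and 291 at 6 h. The tables list only gains of junctions, and the number of introns was not matched. The detection of junctions also depends on depth in ways the matching on TPM only partly covers.

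Junctions predicted to lead to decay could lower the level of their gene. The test set their genes against other genes with a junction, and in CALM/AF10 cells at 10 h the mean log2 change was lower by -0.1191 (permutation p = 0.00711). In GMP at 10 h the difference was -0.42, while the 6 h tables gave no call. Most genes with such a junction were not called lower, only 30 of 142 against 52 of 352 others in CALM/AF10 cells at 10 h. A lower level of the normal transcript for another reason would also raise the share of a rare junction, and that was not tested.

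Sex-linked genes separated the cell types of the time course. Xist stood at 172 ± 16.6 TPM in untreated GMP and 0.0296 ± 0.00844 TPM in untreated CALM/AF10 cells, while the Y-linked gene Ddx3y stood at 0.154 ± 0.0221 and 7.64 ± 0.301 TPM (SD, n = 3). The cell types thus differ in sex as well as in the fusion, and the difference in change cannot be assigned to either. Between the CALM/AF10 lines Ddx3y was 0.385 ± 0.148 TPM in line 1 and 7.07 ± 0.771 TPM in line 2, while Kdm5d, also Y-linked, was 5.89 ± 0.679 and 6.22 ± 0.436 TPM.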
